A study of Homo sapiens with 6 samples.

How the data were processed

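Total RNA of 3 rectal cancer cell lines, called line-61, line-283 and line-503 here after the numbers in their labels, was measured on 6 Affymetrix arrays. Each line has 1 parental array (0 Gy) and 1 array of a derivative that the labels describe as made radio-resistant with caesium gamma radiation up to a total of 80 Gy. Per the labels' protocols, cells grew in RPMI1640 or DMEM with serum and penicillin, RNA was extracted with TRIzol and purified on a column, and high-quality RNA was labelled with biotin. Which line grew in which medium, how the dose was divided and how long after the last exposure the cells were harvested are not given in the sources used here.

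The deposited values are intensities on a linear scale, rounded to whole numbers, 1 per probe set and array. GCOS, Affymetrix Expression Console and RMA are named as tools, per the submitters' processing notes, without versions or roles. RMA usually returns log2 values, and the deposited intensities run from 2 to 14514, so they appear to have been turned back from a log scale; no source used here says so. Median intensities lay between 44 and 49 over the 6 arrays, and they were taken as normalized and kept. The design had been fixed for log2 values, so log2 of each intensity was taken with nothing added. Rounding gives coarse steps at the low end: between 13.9% and 16.4% of the probe sets of an array had an intensity under 10. The number of arrays limits the precision of every comparison.

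Of 33297 probe sets, 19460 carried 1 gene symbol in the platform annotation, 1754 several and 12083 none, and no gene was named from a probe set with several. The gene IDs of 19429 single-gene probe sets matched the RefSeq gene table, which changed 0 symbols. The 18417 genes were each represented by the probe set with the highest mean over the 6 arrays; 769 genes had more than 1 probe set. Control probes could not be picked out by name, so all 33297 probe sets entered the test across probe sets. The 23 genes of the sex chromosomes that could reveal the sex of a donor were left out of all named results. No column of another series was present.

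Irradiated and parental arrays were compared with limma (version 3.58.1 in R 4.3.3), using a linear model of cell line plus irradiation, moderated variances and two-sided tests with Benjamini-Hochberg adjustment. A probe set was called at an adjusted p under 0.05. The cell line was kept as a block because each irradiated derivative comes from the parental line of the same number. To describe that pairing, the deviations of a line's parental and irradiated arrays from their group means were correlated over 11259 genes. The correlations were 0.53 in line-61, 0.66 in line-283 and 0.76 in line-503. Arrays of different lines were not correlated in this way, and line-503 stands apart from both others. These correlations of deviations therefore cannot show that the irradiated arrays of line-61 and line-283 are paired with their own parental arrays. Over genes, the irradiated line-283 array correlated at 0.962 with its own parental array and at 0.946 with parental line-61. The irradiated line-61 array had 0.956 with its own and 0.930 with parental line-283. An exchange of these arrays is taken up further on. The p-values measure the spread of the irradiation difference between 3 lines, with 2 residual degrees of freedom. Within a line there is 1 array per condition, so differences there have no replicate check and no p-value. They were counted at 2-fold or more among genes whose higher value reached the median of all values, a log2 intensity of 5.52. Counts of gene list members within a line had no such floor, so they can include members of low intensity. Lines were compared in the same model, with the 2 arrays of a line in the place of replicates. These are a parental culture and its derivative, not replicate cultures. The p-values between lines therefore rest on how far the irradiation difference varied between lines. A probe set was called at an adjusted p under 0.05 and a 2-fold difference.

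A collection of 30 gene lists was tested with camera (limma) at its preset correlation of 0.01, on 1 probe set per gene. The lists were p53 targets, homologous recombination, non-homologous end joining, excision and mismatch repair, checkpoint signalling, mitosis, DNA replication, replication-dependent histones, interferon-stimulated genes, MHC class I, NF-kB targets, mesenchymal genes, epithelial adhesion, Wnt targets and stem cell genes, enterocyte, goblet and enteroendocrine genes, NRF2, hypoxia and glycolysis, apoptosis, cholesterol biosynthesis, unfolded protein response, drug efflux, receptor tyrosine kinases, cancer-testis antigens, and markers of fibroblasts, leukocytes, endothelium, squamous epithelium and hepatocytes. Only measured genes entered a list. These were 11 of the 18 genes fixed for MHC class I, 16 of 25 for cancer-testis antigens, 17 of 23 for cholesterol biosynthesis and 17 of 22 for homologous recombination, for example. Within each line, the median difference of a list was set against 10000 random lists of the same size drawn from 20 bins of mean expression.

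The genes named in the text follow a rule. For the paired comparison they are the 12 higher and 12 lower genes with the smallest p among those that moved the same way in all 3 lines, by a mean log2 difference of at least 0.5, and that reached the median intensity in the higher group. Within each line they are the 6 genes with the largest difference in each direction. Between lines they would be up to 5 genes per line and direction past the threshold in both contrasts of that line, a condition that 0 genes met. From each list, 2 to 4 members with the largest mean difference were taken, moving the same way in all 3 lines where enough did. Genes named outside this rule are said to be so. The groups, the models, the lists, this rule and most alternatives were fixed before the data were examined; adding 16 to each intensity before taking log2, testing only the annotated probe sets, and recomputing the list medians under other settings were added afterwards.

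The alternatives were a model without the cell line, a further quantile normalization, centring of each array on its median, removal of the dimmest 30% of probe sets, moderated variances with a trend and robust fit, leaving out each line, 1 probe set per gene, the mean of a gene's probe sets, an estimated correlation in camera, fry in place of camera, and thresholds of 1.5-fold and 3-fold. The paired model was tested on simulated data with the real means and the spread of the 33297 probe sets. The changed probe sets were drawn from those with a mean above the median of all values. Of 50 changed at each size it called 0% at 2-fold, 28% at 4-fold, 60% at 8-fold and 76% at 16-fold. At 0.25 of that spread it called 76% at 2-fold and 100% at 4-fold. Each probe set's spread was its own estimate from 2 residual degrees of freedom, so these shares are rough. In simulated data camera called 5 of 5 lists shifted by 0.5 and 1 of 25 unshifted lists. The simulated genes varied independently of each other. In the real lists the estimated correlation was -0.004 for DNA replication, 0.37 for hypoxia and glycolysis and 0.77 for interferon-stimulated genes. The simulation therefore does not check camera's calls on lists whose members vary together. Of 900 medians of random lists, 6.11% fell outside the central 95% of their own reference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for joins, random lists and plots.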

Results

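Gene expression was measured in 3 rectal cancer cell lines, called line-61, line-283 and line-503 here after the numbers in their labels, before and after the selection of a radio-resistant derivative. The parental cells had received 0 Gy and the derivatives a total of 80 Gy of gamma radiation. Each line contributed 1 parental and 1 irradiated array, 6 arrays in all, and the values are RMA-type intensities used here as log2. Over 18417 genes, the 2 arrays of a line correlated at 0.956 in line-61, 0.962 in line-283 and 0.944 in line-503. Line-61 and line-283 resembled each other nearly as closely, with r of 0.936 between their parental arrays and 0.953 between their irradiated arrays. Line-503 stood apart from both, at 0.842 to 0.871; these are correlations across genes, which are not independent replicates. Of the variance of 11670 genes, 75% lay between lines, 10.3% between irradiated and parental arrays and 14.7% in the rest. The irradiation share has 1 degree of freedom and the rest has 2, so part of the 10.3% would arise without any effect of irradiation.

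The first comparison asked which genes differed between irradiated derivatives and their parental lines. ERRFI1, a feedback inhibitor of the EGF receptor (probe set 7912157, chromosome 1), had the smallest p of the genes named by the rule, with a mean log2 difference of 2.0 ± 0.13 (SE, n = 3 lines) and values of 2.16, 1.99 and 1.86 in line-61, line-283 and line-503. MPZL3 was higher by 2.08 ± 0.17, the redox enzyme GLRX by 1.86 ± 0.18, the kinase PIM1 by 1.78 ± 0.21 and the stress cytokine GDF15 by 1.69 ± 0.17. BHLHE40, a transcription factor of the clock and hypoxia responses, had a difference of 1.54, CYP3A5 of 1.5, FHL2 of 1.49, the desmosomal cadherin DSC2 of 1.32, the urokinase receptor PLAUR of 1.22, FGFBP1 of 1.04 and AMIGO2 of 1.03. On the lower side, GINS3 (probe set 7996211, chromosome 16) and GINS1, subunits of the replicative helicase, had differences of -1.38 ± 0.13 and -1.24 ± 0.16. WDHD1, DTL, ASF1B and EXO1, which act in replication, chromatin assembly or DNA end resection, had -1.22, -0.98, -0.94 and -1.19. The mitochondrial aldehyde dehydrogenase ALDH1B1 had -1.36, MFSD1 -1.21, RGMB -1.12, MTARC1 -1.10, NUBPL -1.04 and PSIP1 -0.95.

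None of these 24 genes passed the test: limma called 0 of 33297 probe sets, and the smallest adjusted p was 0.878. At an unadjusted p under 0.05 there were 1796 probe sets (5.39%), 945 higher and 851 lower in irradiated arrays. The model without the cell line as a block also called 0, with 555 at an unadjusted p under 0.05. With 3 pairs an exact test of a single gene cannot go below p = 0.25. Of 18417 genes, 4248 (23.1%) moved the same way in all 3 lines, where chance gives 25% without ties; 162 of them had a mean difference of 2-fold or more upward and 70 downward.

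**Figure D1:**
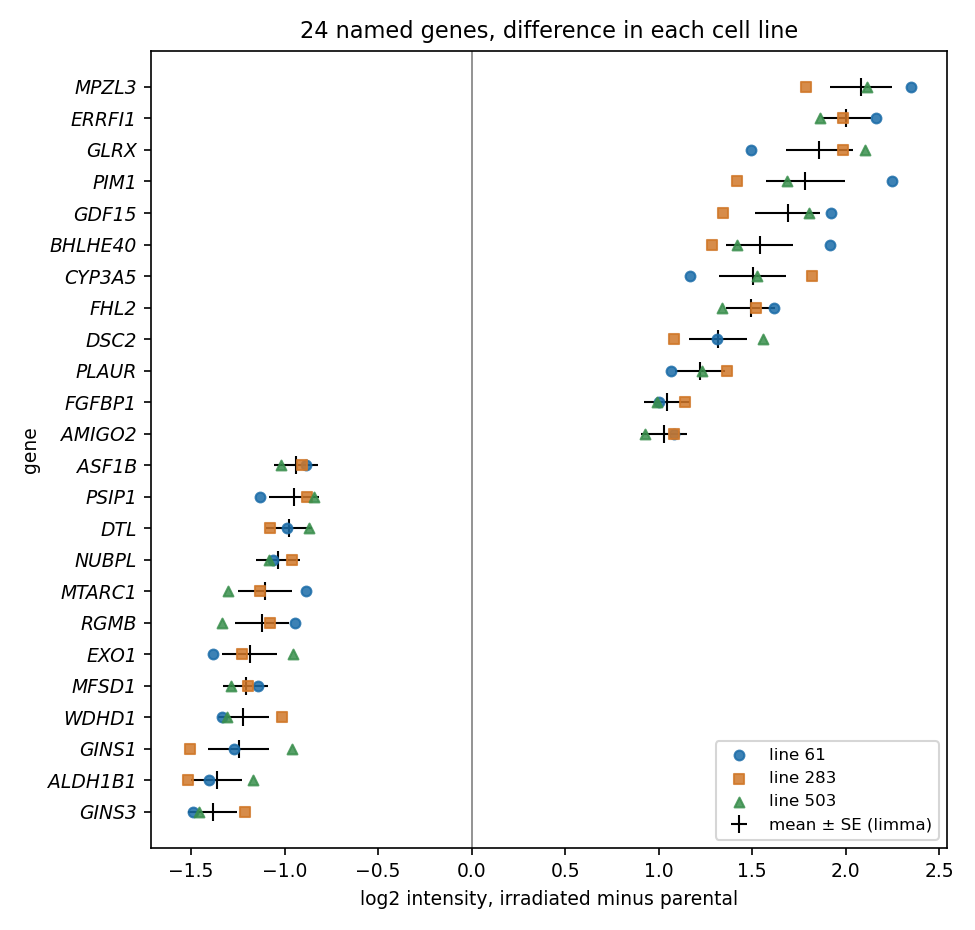
Log2 difference (irradiated minus parental, x axis) of the 24 named genes (y axis) in line-61, line-283 and line-503, with the limma mean and SE as a black mark and bar. ERRFI1 lies at 2.16, 1.99 and 1.86 and GINS3 at -1.49, -1.21 and -1.45; none of the genes passed the adjusted test.

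Genes of hypoxia and glycolysis rose as a list (camera adjusted p = 7.83e-18, 2.75e-25 to 0.444 over its alternatives; adjusted p = 0.444 with an estimated correlation). Of 27 members, 20 were higher in all 3 lines and 0 lower in all 3. The median member was higher by 2.07 in line-61, 1.06 in line-283 and 0.43 in line-503. NDRG1, a hypoxia-induced gene, had a mean difference of 2.69 ± 0.52, the prolyl hydroxylase EGLN3 1.86 ± 0.26 and the collagen prolyl hydroxylase P4HA1 1.62 ± 0.47. Over all probe sets 0 members passed; adjusted over the list alone 8 did, all higher (LDHA, PFKP, SLC2A1, VEGFA, ADM, NDRG1, BNIP3L and EGLN3). The carbonic anhydrase CA12, singled out after its values were seen, went against the list in line-503, at -2.81.

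Genes of DNA replication fell as a list (camera adjusted p = 1.45e-17, 1.04e-18 to 0.302 over its alternatives; adjusted p = 0.302 with an estimated correlation). Of 26 members, 20 were lower in all 3 lines and 0 higher in all 3, with line medians of -0.77, -0.64 and -0.36 in line-61, line-283 and line-503. Besides GINS3 and GINS1, the polymerase subunit POLE2 had a mean of -1.19 ± 0.32 and the sliding clamp PCNA -1.16 ± 0.39, the latter only -0.17 in line-503. Adjusted over the list alone 7 members passed, all lower (MCM3, MCM5, GINS1, GINS2, GINS3, RFC3 and RFC4), and over all probe sets 0 did.

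**Figure D2:**
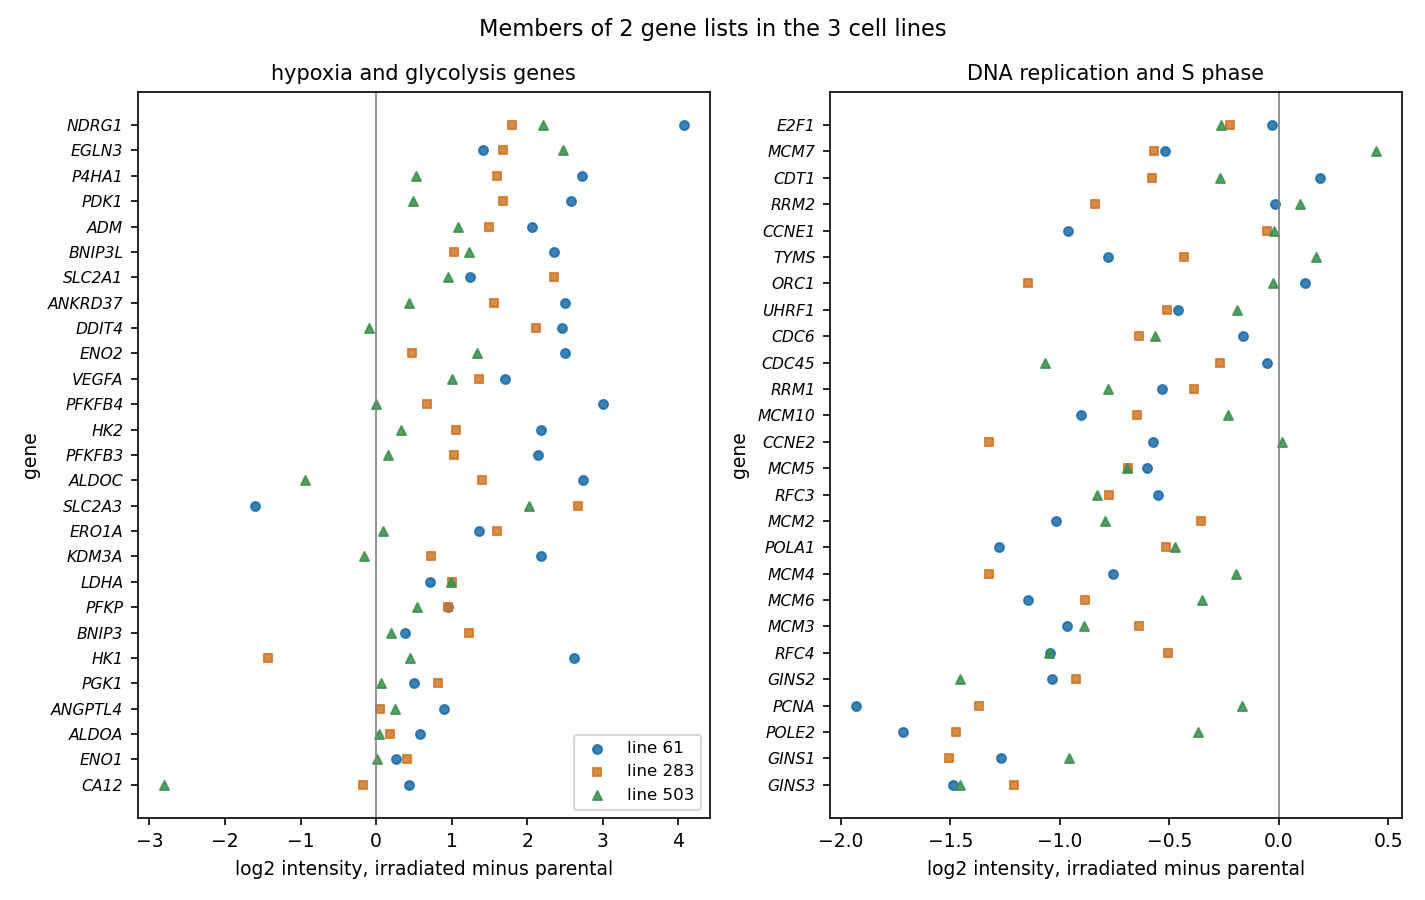
Log2 difference (irradiated minus parental, x axis) of each measured gene (y axis) of the hypoxia and glycolysis list and of the DNA replication list, with 1 point per line. In the first list 20 of 27 genes lie above 0 in all 3 lines, and in the second 20 of 26 lie below 0 in all 3.

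Of the DNA repair lists, homologous recombination and excision and mismatch repair fell and non-homologous end joining was not called (adjusted p = 0.931). Homologous recombination genes fell (adjusted p = 1.54e-06, 1.24e-06 to 0.394 over its alternatives; adjusted p = 0.394 with an estimated correlation), with medians of -0.41, -0.35 and -0.58 in line-61, line-283 and line-503; 8 of 17 members were lower in all 3 lines and 0 higher. XRCC2 had a mean of -0.94 ± 0.21 and the helicase BRIP1 -0.85 ± 0.16; adjusted over the list alone EXO1 passed as the only 1. Excision and mismatch repair genes fell (adjusted p = 0.000807, 0.000387 to 0.394 over its alternatives; adjusted p = 0.394 with an estimated correlation), with 11 of 27 members lower in all 3 lines, among them PARP1 at -0.93 ± 0.14, the uracil glycosylase UNG at -0.86 ± 0.17 and MSH6 at -0.75 ± 0.26. Checkpoint signalling genes fell (adjusted p = 0.00469, 0.000661 to 0.558 over its alternatives; adjusted p = 0.444 with an estimated correlation), with 8 of 18 members lower and 1 higher in all 3 lines, such as the kinase ATR at -0.82 ± 0.17 and the phosphatase CDC25A at -0.79 ± 0.25; without line-283 that call was lost (adjusted p = 0.183). Mitosis genes fell (adjusted p = 1.54e-06, 1.66e-11 to 0.558 over its alternatives; adjusted p = 0.518 with an estimated correlation), with 11 of 26 members lower in all 3 lines and medians of -0.04 in line-61, -0.40 in line-283 and -0.64 in line-503. The kinase PLK1 had -0.65 ± 0.19 and NUF2, a kinetochore protein, -0.57 ± 0.19. Adjusted over the list alone, 0 members of the last 3 lists passed.

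Epithelial adhesion genes rose (camera adjusted p = 1.58e-05, 9.18e-06 to 0.394 over its alternatives; adjusted p = 0.394 with an estimated correlation), with 10 of 20 members higher in all 3 lines and medians of 0.62, 0.22 and 0.49 in line-61, line-283 and line-503. KRT19 had a mean difference of 0.96 ± 0.25, the tight junction gene CLDN4 0.90 ± 0.25, ELF3 0.87 ± 0.31 and the desmosomal DSP 0.73 ± 0.28. Genes of the unfolded protein and amino acid stress response rose (adjusted p = 2.57e-05, 4.21e-08 to 0.558 over its alternatives; adjusted p = 0.518 with an estimated correlation), with medians of 0.39 in line-61, 0.57 in line-283 and -0.06 in line-503; CHAC1, which degrades glutathione, had 1.07 ± 0.17 and EDEM1 0.77 ± 0.15. Receptor tyrosine kinases and ligands rose (adjusted p = 0.0170, 0.000327 to 0.609 over its alternatives; adjusted p = 0.444 with an estimated correlation), with 8 of 32 members higher in all 3 lines and medians of 0.16 in line-61, 0.28 in line-283 and -0.05 in line-503, where 14 members were higher and 16 lower. Among those higher in all 3 lines the phosphatase DUSP4 had 1.48 ± 0.57, EPHA2 1.08 ± 0.39 and EGFR 0.80 ± 0.29. Without line-61 the adjusted p was 0.0577, and without line-283 it was 0.406.

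Weaker calls were made for 3 more lists. Cholesterol biosynthesis genes rose (adjusted p = 0.0170, 1.03e-05 to 0.769 over its alternatives; adjusted p = 0.743 with an estimated correlation), at medians of 0.62 in line-61, -0.14 in line-283 and 0.53 in line-503; INSIG1 had 0.83 ± 0.32, SC5D 0.56 ± 0.12, and TMEM97 -0.58 ± 0.26. Apoptosis regulators rose (adjusted p = 0.0354, 0.0252 to 0.558 over its alternatives; adjusted p = 0.444 with an estimated correlation), a list of both promoters and inhibitors of cell death. Its leading members were the death receptors TNFRSF10A (1.02 ± 0.22) and TNFRSF10B (0.97 ± 0.32) and the inhibitors BIRC2 (1.01 ± 0.16) and MCL1 (0.62 ± 0.18). NF-kB targets and cytokines rose (adjusted p = 0.0379, 0.000699 to 0.755 over its alternatives; adjusted p = 0.755 with an estimated correlation), with TNFAIP3 at 1.04 ± 0.36, LIF at 0.88 ± 0.30 and NFKB2 at 0.76 ± 0.20; the line medians were -0.17, 0.29 and 0.23. The cholesterol call was lost without line-61 (adjusted p = 0.769) and without line-503 (0.257), the apoptosis call without line-61 (0.248) and without line-503 (0.0867), and the NF-kB call without line-283 (0.567) and without line-503 (0.252).

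Interferon-stimulated genes moved in opposite directions in line-61 and line-283. In line-61, 14 of 29 members were 2-fold or more lower in the irradiated array and 0 higher, with a median of -0.67. In line-283, 16 were 2-fold or more higher and 0 lower, with a median of 1.0. The median in line-503 was 0.22. SAMD9 had -2.95 in line-61, 1.93 in line-283 and 2.98 in line-503. OAS1 was among 2 members that were higher in all 3 lines (mean 0.81 ± 0.41), and USP18 was the other (0.22 ± 0.19). Camera called the list as higher (adjusted p = 0.0355, 3.08e-12 to 0.877 over its alternatives; adjusted p = 0.827 with an estimated correlation), a call that without line-283 turned to lower and did not pass (adjusted p = 0.255) and without line-503 was lost (0.276). MHC class I antigen presentation genes, which interferon also induces, were not called (camera adjusted p = 0.480), with 11 of 18 genes measured. Their medians were -0.66, 0.28 and -0.12 in line-61, line-283 and line-503. The immunoproteasome subunit PSMB9 had -1.87 in line-61 and 0.46 in line-283.

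**Figure D3:**
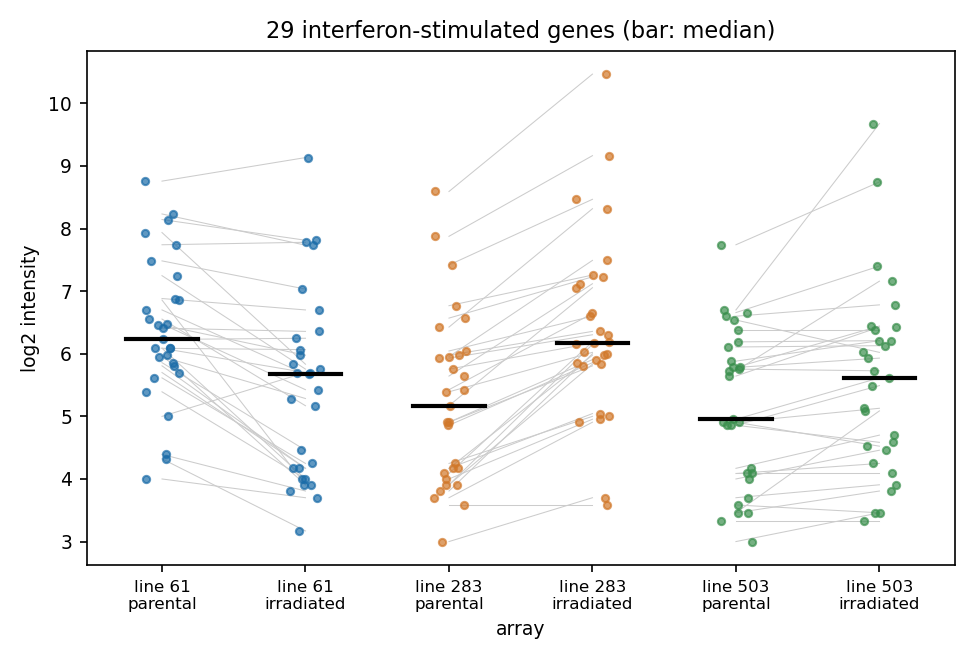
Log2 intensity (y axis) of 29 interferon-stimulated genes in the 6 arrays (x axis); each point is a gene, grey lines join the 2 arrays of a line and black bars are medians. The median gene differed by -0.67 in line-61, 1.0 in line-283 and 0.22 in line-503.

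Markers of squamous epithelium were higher in the irradiated array of line-503. Of 14 members, 8 were 2-fold or more higher there and 0 lower, with a median of 1.16, against medians of -0.12 in line-61 and 0.02 in line-283. KRT4 had 5.24 in line-503, the cornified envelope genes SPRR1A 4.01, IVL 3.74 and SPRR1B 3.50. Camera called the list as higher (adjusted p = 0.00177, 0.000699 to 0.558 over its alternatives; adjusted p = 0.496 with an estimated correlation), and without line-503 the call was lost (adjusted p = 0.516). DSG3, the desmosomal cadherin of stratified epithelia, was the only member higher in all 3 lines, at 3.09, 1.76 and 1.12.

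The remaining 16 lists were not called. Targets of p53 had an adjusted p of 0.439, with 3 of 27 members higher and 2 lower in all 3 lines; CDKN1A, the cell cycle inhibitor, had 0.72 ± 0.14 and TNFRSF10B 0.97 ± 0.32, and without line-283 the list was called as higher (adjusted p = 0.0446, the lowest of its alternatives, which reached 0.965). Non-homologous end joining had 0.931 (PRKDC -0.43 ± 0.12, POLM 0.36 ± 0.14), replication-dependent histones 0.109 (H4C4 -1.19 ± 0.52) and NRF2 and antioxidant genes 0.109 (AKR1C3 1.36 ± 0.27, SOD1 -0.62 ± 0.14). Goblet and secretory genes had 0.0790, with the trefoil peptide TFF1 at 2.79, 3.56 and 0.10 in line-61, line-283 and line-503. Enterocyte genes had 0.0997 (CEACAM7 1.10 ± 0.40, SI -1.18 ± 0.69), enteroendocrine genes 0.602 (SCG3 -0.32 ± 0.12), and Wnt targets with intestinal stem cell genes 0.657 (SOX9 0.40 ± 0.28). Mesenchymal genes had 0.975 (S100A4 0.93 ± 0.30, FN1 -0.33 ± 0.15) and cancer-testis antigens 0.543. Drug efflux and xenobiotic metabolism had 0.993; adjusted over the list alone CYP3A5 passed as the only 1, and the efflux pump ABCC2 had 0.72, 3.25 and 4.53 in the 3 lines. Markers of fibroblasts (0.543), leukocytes (0.993), endothelium (0.931) and hepatocytes (0.729) were not called. Leaving out a line also gave calls for histones without line-61 (lower, adjusted p = 0.00818), and for NRF2 (0.00454), goblet (0.0226) and enterocyte genes (0.0272) without line-503. Median and mean had opposite signs for end joining, Wnt targets, drug efflux and endothelium.

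In all, camera called 14 of 30 lists, 9 higher and 5 lower. With an estimated correlation, and so 2 residual degrees of freedom, 0 were called and 2 had an unadjusted p under 0.05. For DNA replication the estimated correlation, -0.004, was below the preset 0.01, yet the camera p went from 9.70e-19 to 0.0101. The loss of that call therefore does not reflect members that vary together. Fry called 2, homologous recombination (adjusted p = 0.0272) and excision and mismatch repair (0.0350). Within the lines, 12 lists in line-61, 17 in line-283 and 11 in line-503 had medians outside the central 95% of matched random lists, where chance gives 1.5. Not all of these lists are separate gene sets, and their members are not independent.

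**Figure D4:**
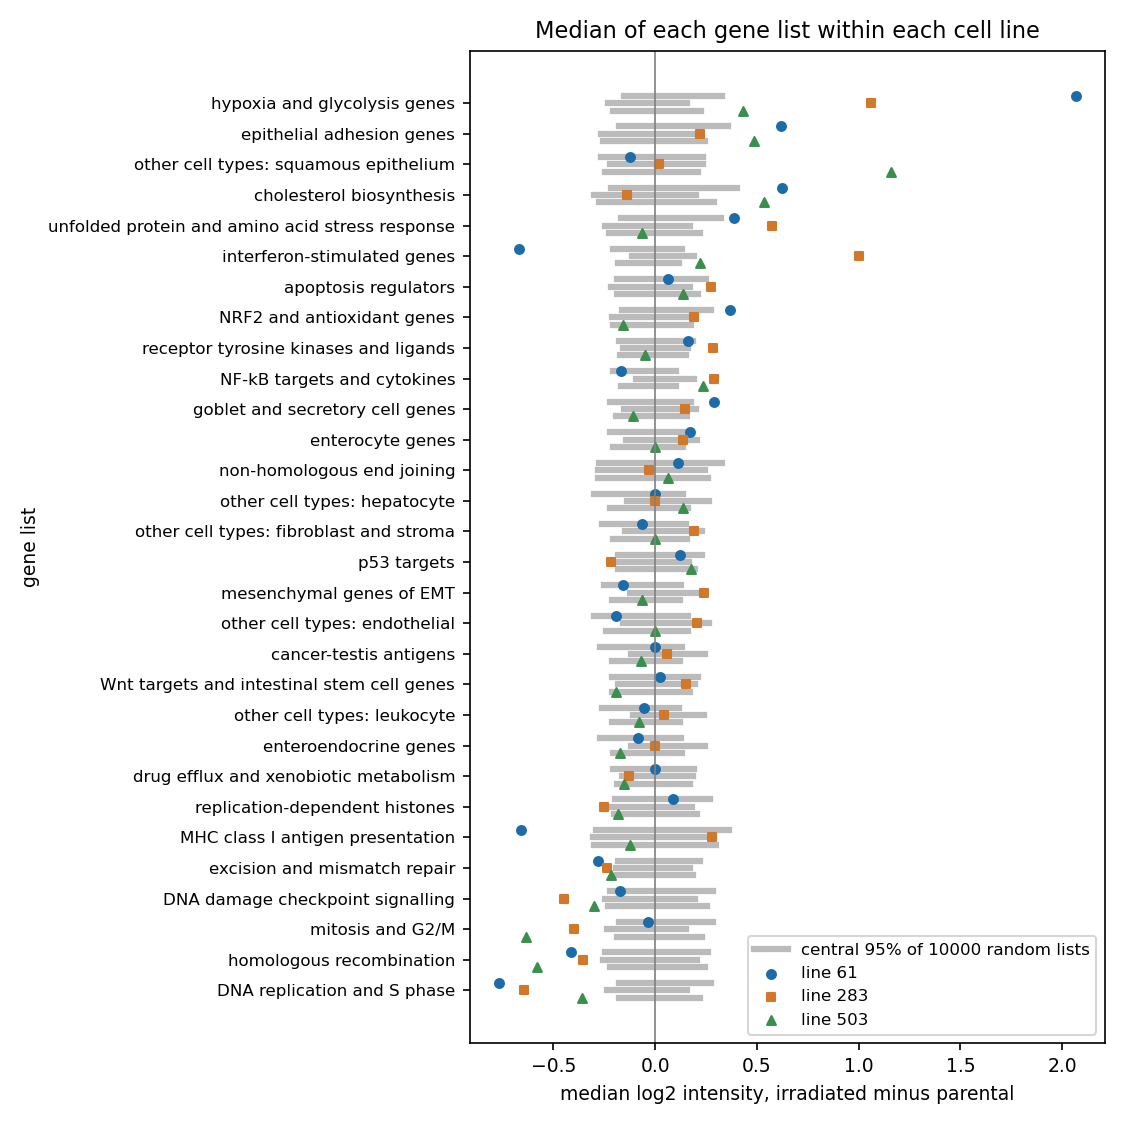
Median log2 difference (irradiated minus parental, x axis) of each of 30 gene lists (y axis) within each line, with the central 95% of 10000 random lists matched on mean expression as a grey bar. The hypoxia list lies at 2.07, 1.06 and 0.43 in line-61, line-283 and line-503, and the DNA replication list at -0.77, -0.64 and -0.36.

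Within line-61, 637 of 11940 genes were 2-fold or more higher and 364 lower in the irradiated array; with 16 added to each intensity 225 were lower. CTSE, an aspartic protease of gastric epithelium, was 33.6-fold higher, NDRG1 16.8-fold, the collagen lysyl hydroxylase PLOD2 14.0-fold, FAM13A 13.4-fold, LCN15 13.3-fold and AOAH 12.7-fold. LCN2, an iron-sequestering lipocalin, had a log2 difference of -3.45, the fatty acid desaturase FADS1 -3.02, SAMD9 -2.95, ANKRD1 -2.85, the histone H4C2 -2.74 and the small nucleolar RNA SNORA71D -2.69. Each within-line value rests on 1 array per condition, so it has no replicate check. The lower intensity was 15 for SAMD9, 18 for ANKRD1 and 27 for PLOD2, where background affects the size of a difference; with 16 added to each intensity, SAMD9 had -2.09, ANKRD1 -2.10 and PLOD2 was 9.16-fold higher.

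Within line-283, 442 of 11574 genes were 2-fold or more higher and 394 lower. The balance turned at 1.5-fold, with 991 higher and 1344 lower, and with 16 added to each intensity 247 were lower at 2-fold. The mucin-type glycosyltransferase GCNT3 was 28.2-fold higher, TM4SF1 27.0-fold, the RAS pathway inhibitor SPRED1 22.4-fold, the actin-bundling PLS3 21.5-fold, EMP1 17.7-fold and the efflux pump ABCG2 17.5-fold. The alcohol dehydrogenase ADH1C had a log2 difference of -5.08, NXPE4 -4.99, the carbonic anhydrase CA1 -4.89, the mucin MUC12 -4.01, the chloride-bicarbonate exchanger SLC26A3 -3.93 and ELAPOR1 -3.50. The lower intensity was 10 for PLS3, 11 for ABCG2, 14 for CA1, 16 for ADH1C and 24 for SPRED1, near the low end of the arrays, so the sizes of these differences are uncertain. With 16 added to each intensity, PLS3 was 8.88-fold, ABCG2 7.74-fold and SPRED1 13.8-fold higher, CA1 had -3.84 and ADH1C -4.12. The enterocyte list as a whole had a median of 0.14 in this line, at percentile 86.9 of random lists.

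Within line-503, 692 of 11694 genes were 2-fold or more higher and 607 lower, the highest counts of the 3 lines at this threshold. At 1.5-fold, 1659 genes were higher in line-503 and 1687 in line-61. The cytokine IL18 was 70.4-fold higher, RPTN 67.8-fold, KRTDAP 62.5-fold, STEAP4 53.4-fold, the small heat shock protein HSPB8 51.5-fold and FLG 45.5-fold; RPTN, KRTDAP and FLG are genes of keratinocyte differentiation. SERPINB11 had a log2 difference of -6.11, ENTPD3 -5.25, JAKMIP2 -5.03, the cystatin CST1 -4.87, the secretory granule protein CHGB -4.65 and FREM2 -4.40. All 12 genes had a lower intensity below the median of all values, down to 5 for IL18, 7 for JAKMIP2 and 8 for STEAP4, so the sizes of these differences depend on background. With 16 added to each intensity, IL18 was 17.5-fold, RPTN 29.6-fold, KRTDAP 40.1-fold, STEAP4 18.5-fold and HSPB8 25.4-fold higher, and SERPINB11 had -4.98, JAKMIP2 -3.41, CST1 -4.15, CHGB -3.75 and FREM2 -3.73.

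The next comparison asked how far the lines changed alike. Line-61 and line-283 shared 162 genes that were 2-fold apart in the same direction, where independent lists would share 29.6, and 48 in opposite directions (27.4 for independent lists). Line-61 and line-503 shared 106 in the same direction (36.7) and 60 in opposite ones (33.8), and line-283 and line-503 shared 102 (25.6) and 76 (25.4). At 3-fold the balance turned for line-61 and line-503, with 11 in the same direction and 13 in opposite ones. The log2 differences correlated across genes at 0.22, 0.08 and 0.06 for these pairs of lines. In all 3 lines, 23 genes were 2-fold or more higher, where 0.672 would be by independent lists, and 5 were lower (0.240). These counts for independent lists treat all genes as equally likely to change. In each pair of lines the genes shared in opposite directions exceeded them too, so the excess overstates a shared response. Among the 23, named here after their values were seen, were the long non-coding RNA UCA1 (mean 2.73), NDRG1 (2.69), EMP1 (2.48), DSG3 (1.99), LMO7 (1.89), EGLN3 (1.86), ADM (1.55), the mitophagy receptor BNIP3L (1.54), VEGFA (1.36) and XDH (1.36). The 5 lower ones were MFSD1, WDHD1, MCM8, ALDH1B1 and GINS3. None of these genes passed the adjusted test of the paired model.

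Line-503 differed from the others in its levels of several intestinal and squamous genes. Averaged over its 2 arrays, line-503 had a log2 intensity of 3.23 ± 0.32 (SD, n = 2 arrays) for the intestinal mucin MUC13, against 11.48 ± 0.17 in line-61 and 11.44 ± 0.00 in line-283. VIL1, the brush border villin, was at 4.67 in line-503, 9.73 in line-61 and 10.60 in line-283, and LGALS4 was at 5.85, 11.23 and 12.27. KRT5, a keratin of basal and squamous cells, was at 10.91 in line-503, 5.39 in line-61 and 5.41 in line-283, and DSC3 at 9.64, 5.62 and 2.99. The squamous list had a median difference of 2.29 between line-503 and line-283 and 2.21 between line-503 and line-61, and the enterocyte list -2.43 and -0.88. The goblet list had -2.25 and -1.22. No list was tested between lines. Between line-503 and line-283, limma called 4 of 14 squamous genes as higher and 0 as lower in line-503. Of 23 enterocyte genes it called 6 as lower and 0 as higher, and of 23 goblet genes 3 as lower and 0 as higher. MUC13, VIL1, LGALS4, KRT5 and DSC3 were chosen from the lists after their values were seen. The labels describe line-503 as they do the other lines; no test here shows whether its identity is as labelled, and it enters every mean over 3 lines and both contrasts with it. Without line-503, limma called 0 probe sets between irradiated and parental arrays, with 1673 at an unadjusted p under 0.05, and camera called 12 lists, 9 of them among the 14 called with all lines.

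**Figure D5:**
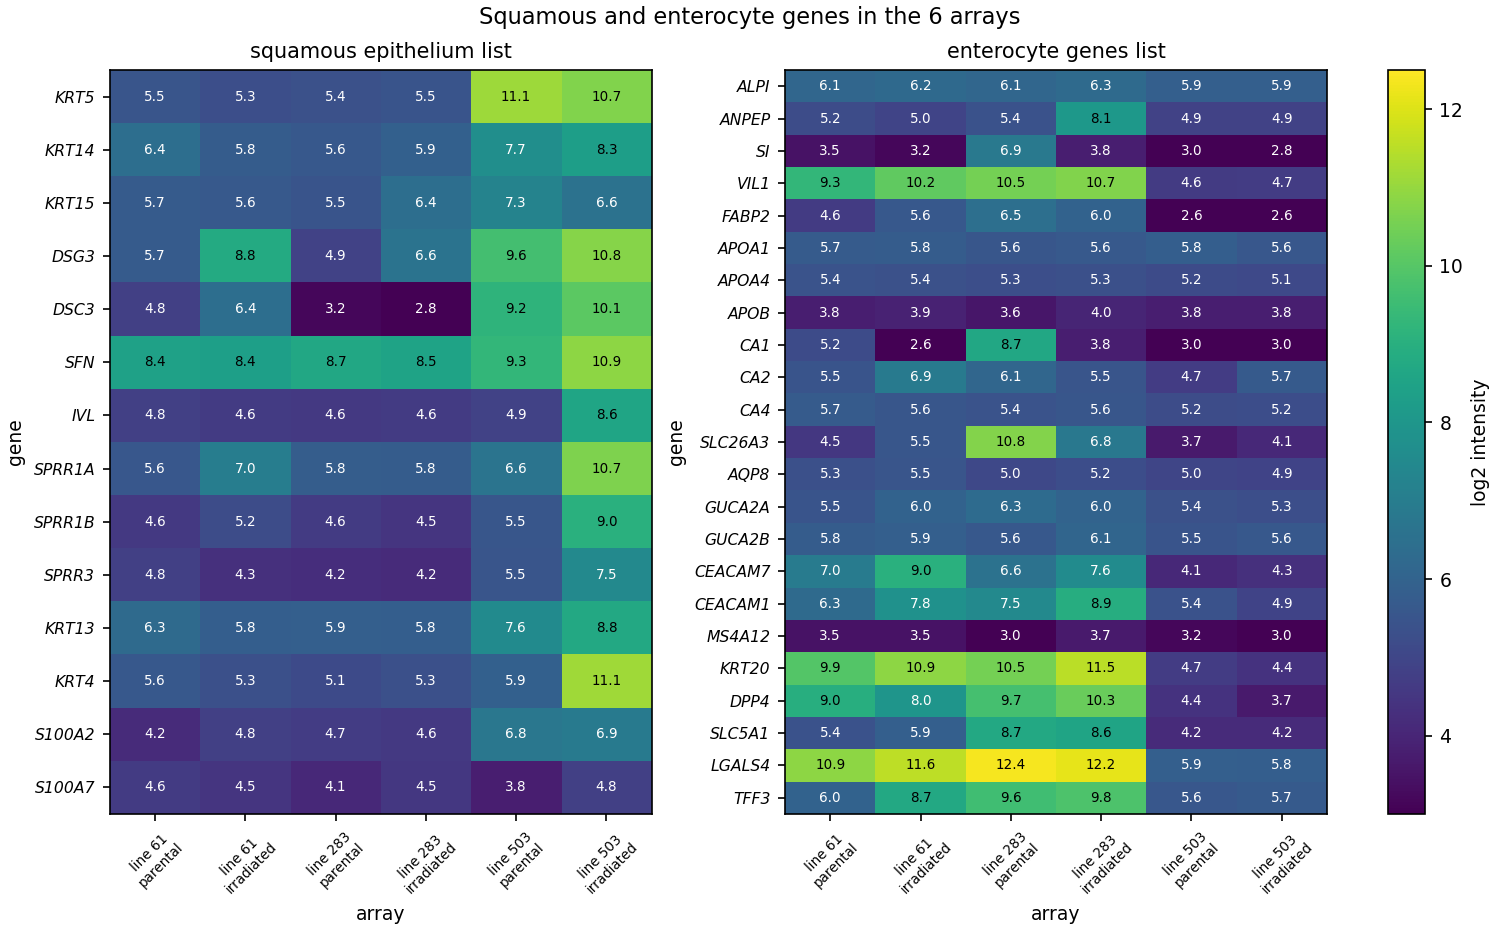
Log2 intensity (colour and printed value) of the measured genes (y axis) of the squamous epithelium and enterocyte lists in the 6 arrays (x axis). KRT5 averages 10.91 in line-503 and 5.39 in line-61, and VIL1 4.67 and 9.73.

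Limma called 1008 probe sets between line-503 and line-283, 610 higher and 398 lower in line-503, from 641 genes; the smallest adjusted p was 0.0314. MUC13, VIL1, LGALS4, KRT5 and DSC3 were among them. Without line-61 the contrast called 0, and the other alternatives called up to 3092. Between line-503 and line-61 it called 0, with 9420 probe sets at an unadjusted p under 0.05 and a smallest adjusted p just above 0.05. The alternatives on all 3 lines called between 354 and 2676. Between line-283 and line-61 it called 0, with 3240 at an unadjusted p under 0.05 (9.73%), and alternatives called up to 34. The F-test over lines called 15, with 8377 at an unadjusted p under 0.05, and up to 2684 under alternatives. Array medians of line-61 lay 0.108 above those of line-283 on the log2 scale.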

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

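For these results the contrast of irradiated and parental arrays had opposite signs in different lines; with 1 array per line and condition, none of the differences between lines was tested. The lists were taken where medians fell outside the central 95% of random lists on opposite sides, and the genes, from those named within a line, where differences of 2-fold or more had opposite signs. Groups of 4 or more samples do not occur, so no search for single outlying samples was made. Of the tests in this part, the exchange of arrays within line-61, the second and the last test of mixed cultures, and the values with 16 added to each intensity were chosen after the result was seen.

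The median of the interferon-stimulated list was 1.67 higher in line-283 than in line-61 and 0.89 higher in line-503 than in line-61. The median of the MHC class I list was 0.94 higher in line-283 than in line-61. For SAMD9 the difference of line-61 minus that of line-283 was -4.88, and minus that of line-503 it was -5.93; with 16 added to each intensity these were -3.33 and -4.89.

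Outside these lists, PLOD2 had a difference 4.86 higher in line-61 than in line-503; with 16 added to each intensity this was 4.14, with -0.94 in line-503, which is under 2-fold. LCN2 gave -5.10 for line-61 minus line-503. ABCG2 was 7.02 higher in line-283 than in line-503, with 4.13 and -2.88 in those lines; its parental intensity in line-283 was 11, so the size is uncertain, and with 16 added the difference was 5.31. SLC26A3 gave -4.93 for line-283 minus line-61, and STEAP4 was 7.49 higher in line-503 than in line-61. For STEAP4 the parental intensity in line-503 was 8, and with 16 added the difference was 5.18, with -0.97 in line-61, which is under 2-fold; SLC26A3 then had 0.67 in line-61, also under 2-fold.

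The opposite course of the interferon genes in line-61 and line-283 could come from exchanged arrays. The values argue against an exchange of the irradiated arrays of these lines. The test took 281 other genes, 4-fold or more apart between the parental arrays. Of these, 62.6% (exact binomial 95% interval 56.7 to 68.3) had the irradiated line-283 array nearer to its own parental array. In line-61, 81.5% did. An exchange of parental and irradiated arrays within line-61 would turn its hypoxia list, which had a median of 2.07, against the other lines. This presumes that the list rises with irradiation in line-61 too. That direction is known only from these same arrays, so the test cannot decide on an exchange within line-61. For cells of line-61 in the irradiated line-283 culture, the test fixed beforehand left the question open: 11 genes on in parental line-61 and off in parental line-283 covered a median 34.6% of the gap from parental line-283 to parental line-61 (bootstrap 2.53 to 67.4), against 63.1% for 16 interferon genes that were 2-fold or more higher in parental line-61. A second test, chosen because the first was open, took 101 genes 4-fold higher in parental line-61, which covered 27.1% (difference from the interferon genes -79.8 to -9.76 percentage points). The last took 438 genes at the same 2-fold threshold as the interferon genes, which covered 26.7% (-78.6 to -17.2). These intervals resample interferon genes as if independent, although the estimated correlation of that list was 0.77, so they are too narrow. Both tests gave a smaller share for the other genes, but they leave cells of line-61 in that culture open. An effect of the irradiation itself and differences in culture conditions stay open and were not tested.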

How the results depend on the processing

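The alternatives with 16 added to each intensity, with annotated probe sets only, and for the list medians were added after seeing the data; the others were planned. The cause of the changes given here was not tested, except where fewer lines, fewer probe sets or another fold threshold enter by construction. The count of 0 probe sets between irradiated and parental arrays (limma, 1796 at an unadjusted p under 0.05) stayed at 0 in all 12 alternatives. Without the replicate block it was 0 as well, with 555 at an unadjusted p under 0.05, and the apoptosis list was no longer called (camera adjusted p = 0.137). The correlations of deviations within lines, 0.53 to 0.76, cannot check the pairing of line-61 and line-283. For the 24 named genes of the paired comparison, 264 of 264 values kept their sign and side of the threshold. These genes were chosen for moving the same way in every line. Leaving out a line, dropping the block or adding 16 to each intensity therefore could not turn their sign. With 0 probe sets called in the alternatives, their side of the threshold was fixed as well. The 264 values are thus not a separate check of these genes. For the genes named within lines 32 values moved and 76 stayed, and for list medians 9 moved and 351 stayed. Of the main results 364 values stayed, 72 moved, 41 lost and 8 gained a call, and 1 reversed. Low intensities limit precision: they are rounded to whole numbers.

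Called lists numbered 14 at the preset correlation, where the degrees of freedom come from the number of genes. With an estimated correlation there were 0, at adjusted p values of 0.302 for replication, 0.394 for homologous recombination, excision repair and epithelial adhesion, 0.444 for hypoxia, checkpoint, apoptosis and receptor tyrosine kinases, 0.496 for squamous, 0.518 for mitosis and unfolded protein response, 0.743 for cholesterol, 0.755 for NF-kB and 0.827 for interferon genes. Fry called 2, homologous recombination (0.0272) and excision repair (0.0350), and gave 0.0781 for replication, 0.337 for hypoxia and epithelial adhesion, 0.558 for checkpoint, mitosis, apoptosis, unfolded protein response and squamous, 0.609 for receptor tyrosine kinases, 0.718 for cholesterol, 0.722 for NF-kB and 0.877 for interferon genes. With 16 added, interferon genes had 0.0542 and NF-kB 0.0964, and with the mean of all probe sets NF-kB had 0.0511. Enterocyte genes were called without dim probe sets (0.0327), and goblet genes with a further quantile normalization (0.0458) or centring (0.0493).

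Leaving out each line in turn gave adjusted p from 0.0446 to 0.965 for p53 targets, 0.000661 to 0.183 for checkpoint, 3.08e-12 to 0.276 for interferon genes (reversed without line-283, 0.255), 0.0272 to 0.769 for enterocyte, 0.0226 to 0.713 for goblet, 0.00454 to 0.965 for NRF2, 0.0446 to 0.248 for apoptosis, 1.03e-05 to 0.769 for cholesterol, 0.000699 to 0.567 for NF-kB, 0.000327 to 0.406 for receptor tyrosine kinases, 0.00818 to 0.696 for histones and 0.000699 to 0.516 for squamous genes. The number of called lists was 11 to 12.

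Between lines, the alternatives were, in order, no irradiation term, further quantile normalization, centring, no dim probe sets, a trend and robust fit, 1 probe set per gene, and annotated probe sets only. Line-283 and line-61 gave 16, 14, 17, 34, 18, 4 and 8 called. Line-503 and line-61 gave 1786, 1644, 2166, 2676, 2099, 1104 and 1332, and 354 with 16 added. Line-503 and line-283 gave 2093, 2052, 2563, 3092, 2528, 1630 and 1852, and 0 without line-61. The F-test gave 1509, 1159, 1911, 2684, 1773, 1006 and 1183.

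Within line-61, 1687 genes were higher and 1232 lower at 1.5-fold, 163 and 81 at 3-fold, 1075 and 588 over all probe sets, and 225 lower with 16 added. Within line-283, 991 were higher and 1344 lower at 1.5-fold, 166 and 90 at 3-fold, 608 lower over all probe sets and 247 lower with 16 added. Within line-503, 1659 were higher and 1456 lower at 1.5-fold, and 271 and 240 at 3-fold.

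Genes shared in the same and opposite directions by line-61 and line-283 were 624 and 214 at 1.5-fold, 28 and 10 at 3-fold, 102 and 31 with 16 added, and 79 opposite over all probe sets. Line-61 and line-503 shared 505 and 324 at 1.5-fold, 11 and 13 at 3-fold, and 67 in the same direction with 16 added. Line-283 and line-503 shared 402 and 304 at 1.5-fold, 23 and 14 at 3-fold, and 63 and 45 with 16 added. In all 3 lines, 98 genes were higher and 57 lower at 1.5-fold, 3 and 0 at 3-fold, and 2 lower with 16 added.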

Other observations

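The gene families in this paragraph and the next were chosen after the values were seen, so their percentiles describe these arrays only. Small proline-rich genes, which build the cornified envelope of squamous cells, were 2-fold or more higher in the irradiated array of line-503 in 9 of 9 cases, with a median of 3.50 (percentile 100 of 10000 matched random lists), against 0.10 in line-61 and -0.08 in line-283; with 16 added to each intensity the line-503 median was 2.33, still with 9 of 9. SPRR2G had 4.56 and SPRR2A 4.07. Late cornified envelope genes had a median of 0.75 in line-503, with 4 of 15 at 2-fold or more higher. The counted copies of the small nucleolar RNA SNORD116, from an imprinted cluster, were lower there, 7 of 7 by 2-fold or more with a median of -2.92. The copies are similar in sequence, so their probe sets may not be separate measurements. With 16 added to each intensity their median was -2.56.

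Zinc finger genes named ZNF had a median of -0.27 in line-283, where 43 of 327 were 2-fold or more lower and 2 higher, and 0.14 in line-503, where 19 were higher and 4 lower. ZNF136 had -2.22 in line-283 and ZNF114 had 3.71 in line-503. With 16 added to each intensity, 20 were lower and 2 higher in line-283, with the same sign of the median. Metallothionein genes, which bind zinc and copper, had medians of -0.54, -0.46 and -0.27 in line-61, line-283 and line-503, at percentiles 0.120, 0.345 and 4.62; MT2A had -1.01, -0.99 and -0.27. The signs of these medians held under centring and a further quantile normalization.

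Of the tests in the following paragraphs, those of intensity bias, of cycling cells, of the identity of the irradiated line-503 array and of the number of called probe sets were chosen after the result was seen.

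The hypoxia list was higher and the replication list lower in every line. A bias that depends on mean intensity would move matched random lists as far, but the lowest percentile of the hypoxia list over the 3 lines was 99.99 and the highest of the replication list 0. A smaller share of cycling cells might lower mitosis genes as far as replication genes, a premise that was not tested. The replication median minus the mitosis median was -0.73 (bootstrap interval over genes -1.22 to -0.43) in line-61 and -0.24 (-0.55 to -0.07) in line-283. In line-503 it was 0.28 (-0.15 to 0.49). The intervals resample genes from 1 array per condition and do not measure the spread between cultures. A smaller share of cycling cells therefore stays open in all 3 lines. Denser cultures at harvest, with less oxygen and fewer cells in S phase, are a candidate explanation that no value here can separate from the irradiation, since each line has 1 array per condition.

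The squamous genes of line-503 may reflect further differentiation of a line whose squamous list was higher than in the other lines over its 2 arrays, or a change of the culture. The irradiated line-503 array correlated with parental line-503 by 0.0789 more than with any array of line-61 and line-283 (0.944 against at most 0.865), which argues against a sample of those lines. Replacement of most cells by an unrelated population cannot be told apart. Here 158 genes that marked parental line-503 against the other lines by 8-fold or more had a median difference of -1.15 (-1.47 to -0.79). The limits set beforehand were -3 for replacement and -1 against it. The -3 holds for nearly complete replacement, and a partial one would lower these genes less. The genes were also chosen for a high parental line-503 value, which favours a fall. They mark line-503 only against line-61 and line-283, so an unrelated population could share some of them. Of these genes 24 (15.2%) were 8-fold or more lower and 66 (41.8%) stayed within 2-fold. A biological effect of the irradiation remains open and was not separated from these.

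Only 4 splits of the 6 arrays part all 3 pairs, too few for a share under 0.05; each of the others exchanges the arrays of 1 line. Called probe sets were 0 in the real split and at most 0 in the others, so 4 of 4 gave as many. Probe sets at an unadjusted p under 0.05 were 1796 in the real split and at most 1486 in the others, and called lists were 14 and at most 6, so 1 of 4 splits, the real one, gave as many in each case.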
